A study of Mus musculus with 40 samples.

How the data were processed

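RNA was measured in mouse oocytes and zygotes, as total RNA and as RNA from a polysome fraction, which is enriched for messenger RNA bound by several ribosomes. The 40 libraries fall into 10 groups of 4. They cover 5 types of cell in 2 fractions: denuded oocytes matured in vitro (IVM), oocytes matured in vitro as cumulus-oocyte complexes (COC), oocytes matured in vivo (IVO), zygotes from in vitro matured and fertilized oocytes (IMZ), and in vivo zygotes (IVZ). Per the labels' protocols the libraries were made with the SMARTer Stranded Total RNA-Seq Kit v2 for picogram inputs. The submitters' processing notes name DRAGEN, with no version, and the genome build GRCm39. The alignment settings, the gene annotation, the strand setting of the counting and the authors' statistical test are not given in the sources used here. The labels do not say whether replicates came from separate animals or collections, so p-values measure the spread between these samples, which may be partly technical. Nor do they say whether the polysomal and total library of 1 sample code came from 1 collection, so the fractions were fitted and split as unpaired.

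The authors deposited 8 tables, one for each of 4 comparisons in each fraction. Per the file headers, each table gives an RPKM value per gene and library, which is a read count scaled to gene length and to library size. Each deposited table also holds the authors' log2 fold change and the authors' p-value per gene. A table lists only genes at 0.2 RPKM or more in each of its 8 libraries, so a gene silent in 1 group is not seen. Per the file headers, 2 polysomal libraries, IVM replicate 1 and IVZ replicate 1, were excluded by the authors from their analysis after a principal component analysis. Both were kept here, and the fits without them are among the alternatives.

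Read depth was recovered from the steps between low RPKM values, with exonic lengths from GENCODE release M21. That annotation belongs to an older genome build than the authors' and was used for lengths and GC content only, with no coordinates. The method found the depth of 10 of 10 simulated libraries within 1%. It gave 46.6 to 63.2 M reads for the 20 total RNA libraries. In the polysomal fraction it gave a depth for 12 of 20 libraries, from 3.14 to 25.6 M, and the depth of the others is unknown.

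No counts were used, so each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a variance trend on mean expression, the 8 libraries of 1 table and no covariate. A fold change on this scale understates the change of genes at low RPKM. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The plan assumed counts for the test of polysomal against total RNA. With RPKM values it was run instead as a limma interaction of condition and fraction over 16 libraries, and gene lists were tested on log2(RPKM + 1) in place of log2 CPM. Tables were normalized separately, so groups were tested only within a table, except in that interaction, in the fit of all oocyte groups and in the comparison of oocytes with zygotes.

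The groups, the comparisons, 25 gene lists, the rule for naming genes and the first set of alternatives below were set before the data were examined. The rule took the 6 genes with the highest and the 6 with the lowest log2 fold change among those called in each comparison, leaving out predicted and clone-named genes. It added up to 4 members with the smallest p of each list described, and always Ccnb1, Mos, Btg4, Gdf9, Zp3, Dppa3, Nlrp5 and Has2 where measured. Has2 was in none of the tables, and some genes that the rule takes are not reported here. Genes named outside this rule are said to be chosen after their values were seen. Lists with at least 5 tested members were tested with camera in limma, with an inter-gene correlation preset at 0.01 and, as an alternative, estimated per list. Members of a list were also counted after adjustment over the list alone.

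The alternatives were another scaling (median of ratios), the replicate number as a block, 1 fit of all oocyte groups, each library left out in turn, other thresholds, and for lists a rank-based test. Alternatives added after the data were seen were a pseudocount of 0.1, a mean RPKM of at least 1, array weights, no variance trend, pairing of the polysomal and total library of a sample code, removal of each library's trend on transcript GC or on transcript length, and Benjamini-Hochberg adjustment of the authors' deposited p-values. The comparison of the changes in oocytes and zygotes was also added after the data were seen. The fits were tested on simulated data in which known genes were changed on the log2(RPKM + 1) scale, with noise independent between genes. A gene at low RPKM needs a larger fold change in RPKM to reach such a change. Noise shared by genes of a library was not simulated, so recovery may be overstated. For IVM against IVO in total RNA, 55 of 67 genes changed 1.5-fold and 62 of 67 genes changed 2-fold were recovered among 10996 genes. For the same comparison in polysomal RNA, 0 of 67, 2 of 67 and 54 of 66 genes changed 1.5-fold, 2-fold and 4-fold were recovered among 5093 genes.

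Replication-dependent histones, ribosomal protein genes with pseudogenes, mitochondrial genes with nuclear copies, and the Obox, Pramel, Tex19 and Dcpp families have near-identical copies, and their values are uncertain because the authors' handling of shared reads is not given in the sources used here. The same holds for overlapping and antisense genes.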

Results

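Total RNA and polysomal RNA were profiled in mouse oocytes and zygotes to compare maturation in vitro with maturation in vivo, in zygotes together with fertilization. Each of the 10 groups held 4 libraries. Total RNA libraries held a median of 53.7 M reads. The polysomal libraries whose depth could be recovered held a median of 9.46 M, and IVZ replicate 1 was the shallowest of these at 3.14 M. Libraries of total RNA were alike, with Spearman correlations of 0.983 to 0.997 within the IVM and IVO table. In polysomal RNA the same table gave 0.651 to 0.963. Values are RPKM as mean ± SD with n = 4, fold changes are on the log2(RPKM + 1) scale with their standard errors, and adjusted p-values are from limma.

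In total RNA, denuded oocytes matured in vitro were compared with oocytes matured in vivo. Among the genes that rose were Rilpl1, a RILP-like adaptor protein, and the germ cell gene Tex19.2. Rilpl1 (ENSMUSG00000029392) stood at 10.5 ± 2.68 in IVM and 1.84 ± 0.556 in IVO oocytes, a log2 fold change of 2.01 ± 0.19 (limma adjusted p = 0.00493). Tex19.2 rose from 0.458 ± 0.125 to 2.62 ± 1.2. The histone gene H2ac10 rose from 1.74 ± 0.452 to 4.72 ± 0.972, Dcpp2 by 0.88 ± 0.14, and the zinc finger gene Zfp707 by 0.82 ± 0.08. Lcp1 (ENSMUSG00000021998), which encodes the actin-bundling protein L-plastin, rose from 2.24 ± 0.265 to 4.93 ± 0.256 (limma adjusted p = 0.00493).

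The lowest p belonged to C130074G19Rik (ENSMUSG00000039349), a clone-named gene chosen after its values were seen. It stood at 2.70 ± 0.199 in IVM and 0.426 ± 0.061 in IVO oocytes, a log2 fold change of 1.37 ± 0.06 (limma adjusted p = 2.66e-05). Over all 10996 genes, 56 rose and 0 fell in IVM oocytes, and 1198 had an unadjusted p under 0.05. By the authors' deposited table, with their p-values adjusted here, 98 genes rose and 6 fell. Of all genes, 805 (7.32%) had groups that did not overlap, in either direction. Chance gives 2.86% for a single gene, but genes vary together, so a higher share is not by itself evidence of a change. The count was 11 after median-of-ratios scaling, with Tex19.2 and Dcpp2 no longer past the threshold, and 20 after removal of each library's trend on transcript length, with Tex19.2, Dcpp2 and H2ac10 no longer past it at log2 fold changes of 1.20, 0.78 and 0.90. It fell to between 7 and 12 when any 1 library other than IVM replicate 2 was left out, and was 52 without IVM replicate 2. With the replicate number as a block 1 gene was called, so the size of the count depends on single libraries and on the fit.

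The well-known maternal messengers did not pass the test in this comparison. The meiotic regulator Ccnb1 stood at 221 ± 11.8 and 230.4 ± 16.3 RPKM in IVM and IVO oocytes, and the kinase gene Mos at 145 ± 16.8 and 135 ± 27.9. Btg4, a factor of maternal mRNA decay, differed by -0.10 ± 0.11, the zona gene Zp3 by 0.18 ± 0.14, Dppa3 by 0.07 ± 0.11 and Nlrp5 by 0.08 ± 0.15. The secreted factor Gdf9 stood at 1459 ± 21.1 against 1191 ± 122 (limma adjusted p = 0.357).

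Of the gene lists, replication-dependent histones were higher as a group in IVM oocytes and mitochondrially encoded mRNAs were lower. The 49 measured histone genes had a median log2 fold change of 0.32 (camera adjusted p = 8.84e-07), with an adjusted p = 0.331 with an estimated correlation. Over all genes 1 histone gene rose and 0 fell, and adjusted over the list alone 5 rose. H2bc1 stood at 97.8 ± 11.7 against 67.2 ± 7.08, and H3c1 at 29.3 ± 3.68 against 20.1 ± 2.53. The 13 mitochondrial mRNAs had a median of -0.38 (camera adjusted p = 2.13e-07), with an adjusted p = 0.331 with an estimated correlation. None passed over all genes, 3 had an unadjusted p under 0.05, and adjusted over the list alone 1 fell. mt-Nd3 stood at 57.9 ± 6.02 against 81.2 ± 12.3, and mt-Nd6 at 189 ± 46 against 284 ± 88.5. The mitochondrial list lay 0.49 and 0.51 above the mean of the oocyte libraries in IVO replicates 1 and 3 and 0.29 above it in IVM replicate 2, while the histone list lay at -0.37, -0.33 and -0.12 in the same libraries.

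Spindle and kinetochore genes were lower as a group, with a median of -0.09 over 41 genes (camera adjusted p = 1.08e-05, and adjusted p = 0.572 with an estimated correlation). None passed over all genes, while adjusted over the list alone 3 fell and 1 rose. Ckap5, a microtubule polymerase, stood at 38.8 ± 0.832 against 46.9 ± 1.68, and the kinetochore gene Ndc80 at 20.9 ± 1.93 against 26.7 ± 1.66. Rangap1, which encodes the GTPase-activating protein of Ran, went the other way at 3.82 ± 1.44 against 1.35 ± 0.325. Maternal mRNAs known to be activated during maturation had a median of -0.08 over 34 genes (camera adjusted p = 0.000367, and adjusted p = 0.223 with an estimated correlation), with 0 passing over all genes, 3 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Among them Cenpe differed by -0.44 ± 0.15 and Plat by -0.24 ± 0.11.

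Oocytes matured in vitro inside their cumulus-oocyte complexes were next compared with in vivo oocytes in total RNA. Flna (ENSMUSG00000031328), which encodes the actin crosslinker filamin A, rose from 0.914 ± 0.0493 in IVO to 2.95 ± 0.424 in COC oocytes, by 1.04 ± 0.08 (limma adjusted p = 0.00323). It was the 1 gene called among 10981, with 0 genes lower, and 777 had an unadjusted p under 0.05. By the authors' deposited table, with their p-values adjusted here, 18 genes were higher and 10 lower. Rilpl1 stood at 10.3 ± 5.09 in COC oocytes, as high as in IVM oocytes, but its libraries spread from 6.8 to 17.7 and it did not pass (log2 fold change 1.92 ± 0.26, limma adjusted p = 0.122). Tnfsf10, the gene of the death ligand TRAIL, stood at 3.24 ± 1.32 against 0.677 ± 0.0971, and Grem1, a BMP antagonist made by cumulus cells, at 1.31 ± 0.504 against 0.346 ± 0.133 (limma adjusted p = 0.423). Rilpl1, Tnfsf10 and Grem1 were chosen after their values were seen, and each had an adjusted authors' p under 0.05 in the authors' deposited table.

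In COC oocytes 6 lists were called, among them the 4 called in denuded oocytes, each in the same direction. Both comparisons use the same IVO libraries, so this is not an independent repeat, and no value for unchanged groups was computed for lists. The 49 histone genes had a median log2 fold change of 0.33 (camera adjusted p = 2.52e-10, and adjusted p = 0.157 with an estimated correlation). None passed over all genes, 19 rose and 1 fell at an unadjusted p under 0.05, and adjusted over the list alone 14 rose. H4c8 stood at 37.8 ± 3.98 against 22.7 ± 3.12 and H3c7 at 207 ± 20.6 against 138 ± 21.4. The mitochondrial mRNAs had a median of -0.28 (camera adjusted p = 9.79e-07, and adjusted p = 0.361 with an estimated correlation), with 0 passing over all genes and, adjusted over the list alone, 1 lower. mt-Atp8 stood at 142 ± 15.8 against 199.8 ± 25.2, and mt-Atp6 at 599.9 ± 35.8 against 982 ± 308. Around the mean of the oocyte libraries the mitochondrial list lay at 0.49, 0.07, 0.51 and -0.11 in IVO replicates 1 to 4. In COC replicates 1 to 4 it lay at -0.13, -0.03, -0.14 and -0.14, so IVO replicate 4 lay among the COC libraries.

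Spindle and kinetochore genes had a median of -0.13 in COC oocytes (camera adjusted p = 5.94e-09, and adjusted p = 0.361 with an estimated correlation), with 0 passing over all genes and, adjusted over the list alone, 4 lower. Ckap5 stood at 34.4 ± 1.28 against 46.9 ± 1.68 and the kinesin gene Cenpe at 58.7 ± 6.75 against 90.8 ± 10.8. The other lists called were lower by smaller medians, each with 0 genes passing over all genes. They were maturation-activated mRNAs (median -0.05, camera adjusted p = 0.0129, and adjusted p = 0.361 with an estimated correlation, with 1 lower when adjusted over the list alone), cytosolic ribosomal proteins (median -0.07, camera adjusted p = 0.00379, and adjusted p = 0.844 with an estimated correlation, with 0 adjusted over the list alone), and chromatin regulators (median -0.03, camera adjusted p = 0.0237, and adjusted p = 0.368 with an estimated correlation, with 0 adjusted over the list alone). Maturation-activated mRNAs were no longer called after removal of the GC trend (median -0.06, camera adjusted p = 0.056), nor chromatin regulators after removal of the length trend (median -0.05, camera adjusted p = 0.0985), although neither median came nearer to 0. Rpl6 differed by -0.38 ± 0.10 and the chromatin remodeller Chd4 by -0.30 ± 0.09. Of the always-named genes, Nlrp5 differed by -0.30 ± 0.12, Zp3 by -0.28 ± 0.13, Gdf9 by 0.13 ± 0.11 and Mos by 0.14 ± 0.14, while Ccnb1, Btg4 and Dppa3 lay within 0.07 of 0; none passed.

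Both in vitro groups were compared with the same IVO libraries. No gene was called in both, where 0.00512 is the number for independent lists and simulated unchanged groups gave 0. Only 1 gene was called in COC oocytes, so this count cannot show whether changes were shared. By the authors' adjusted p, Rilpl1, Tnfsf10, Tex19.2 and H2ac13 were higher in both and Btn1a1 lower. The authors' log2 fold changes were 2.44, 2.20, 2.46, 1.74 and -1.46 in IVM and 2.44, 2.22, 2.15, 1.74 and -1.80 in COC. By that p Flna passed only in COC, and C130074G19Rik and Lcp1 only in IVM. These genes were picked here after their values were seen. The limma fold changes of the 10937 genes in both tables had a Pearson correlation across genes of 0.767. Simulated unchanged groups that share the IVO libraries gave 0.504, and genes are not independent replicates. The covariance was 0.018 beside a simulated 0.00669. The simulated values are given without a spread, so they cannot decide whether unchanged groups would reach a correlation of 0.767. With the IVO libraries split into pairs, the correlation ran from -0.241 to 0.588 and 0 to 2 genes were called in both. In polysomal RNA the correlation was 0.346 beside a simulated 0.501, and the covariance 0.0518 beside 0.0813.

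The direct comparison of denuded with cumulus-enclosed maturation in total RNA called 5 genes. C130074G19Rik was higher in IVM than in COC oocytes, at 2.70 ± 0.199 against 0.81 ± 0.148 (limma adjusted p = 0.000968), and so was Lcp1, at 4.93 ± 0.256 against 2.67 ± 0.218 (limma adjusted p = 0.00582). Zfp707 was higher by 0.65 ± 0.08, and Uqcrc1, a core subunit of respiratory complex III, stood at 1.67 ± 0.0535 against 0.725 ± 0.0676. Flna was lower in IVM oocytes, at 1.14 ± 0.0953 against 2.95 ± 0.424 (limma adjusted p = 0.00388). Of 11152 genes, 4 were higher and 1 lower, and 630 had an unadjusted p under 0.05. By the authors' deposited table, with their p-values adjusted here, 30 were higher and 4 lower. Against IVO oocytes, C130074G19Rik in COC oocytes stood at 0.81 ± 0.148 and 0.426 ± 0.061 (limma adjusted p = 0.423).

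Plec, Dbn1 and Tes were chosen after their values were seen, and none passed the test. Plec, the gene of the linker plectin, differed by -0.45 ± 0.07 between IVM and COC oocytes (limma adjusted p = 0.0732). The actin-binding drebrin gene Dbn1 differed by -0.87 ± 0.17 and Tes, which encodes the adhesion protein testin, by -0.51 ± 0.12. Cytosolic ribosomal protein genes were higher as a group in IVM oocytes, with a median of 0.12 over 81 genes (camera adjusted p = 5.38e-09, and adjusted p = 0.694 with an estimated correlation). None passed over all genes, and adjusted over the list alone 5 were higher. Rpl7 stood at 37.4 ± 2.57 against 28.3 ± 2.55. Heat shock and unfolded protein response genes had a median of 0.09 (camera adjusted p = 0.0193, and adjusted p = 0.679 with an estimated correlation), with 0 passing over all genes and, adjusted over the list alone, 2 higher, among them the heat shock factor gene Hsf2 at 0.44 ± 0.07 and the chaperone gene Hsph1 at 0.43 ± 0.07. The rank-based test did not call this list (adjusted p = 0.0825). Zp3 differed by 0.46 ± 0.11 and Nlrp5 by 0.38 ± 0.13, Gdf9 by 0.17 ± 0.08, and Ccnb1, Mos, Btg4 and Dppa3 by -0.09, -0.02, -0.09 and 0.00, all short of the threshold.

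**Figure D1:**
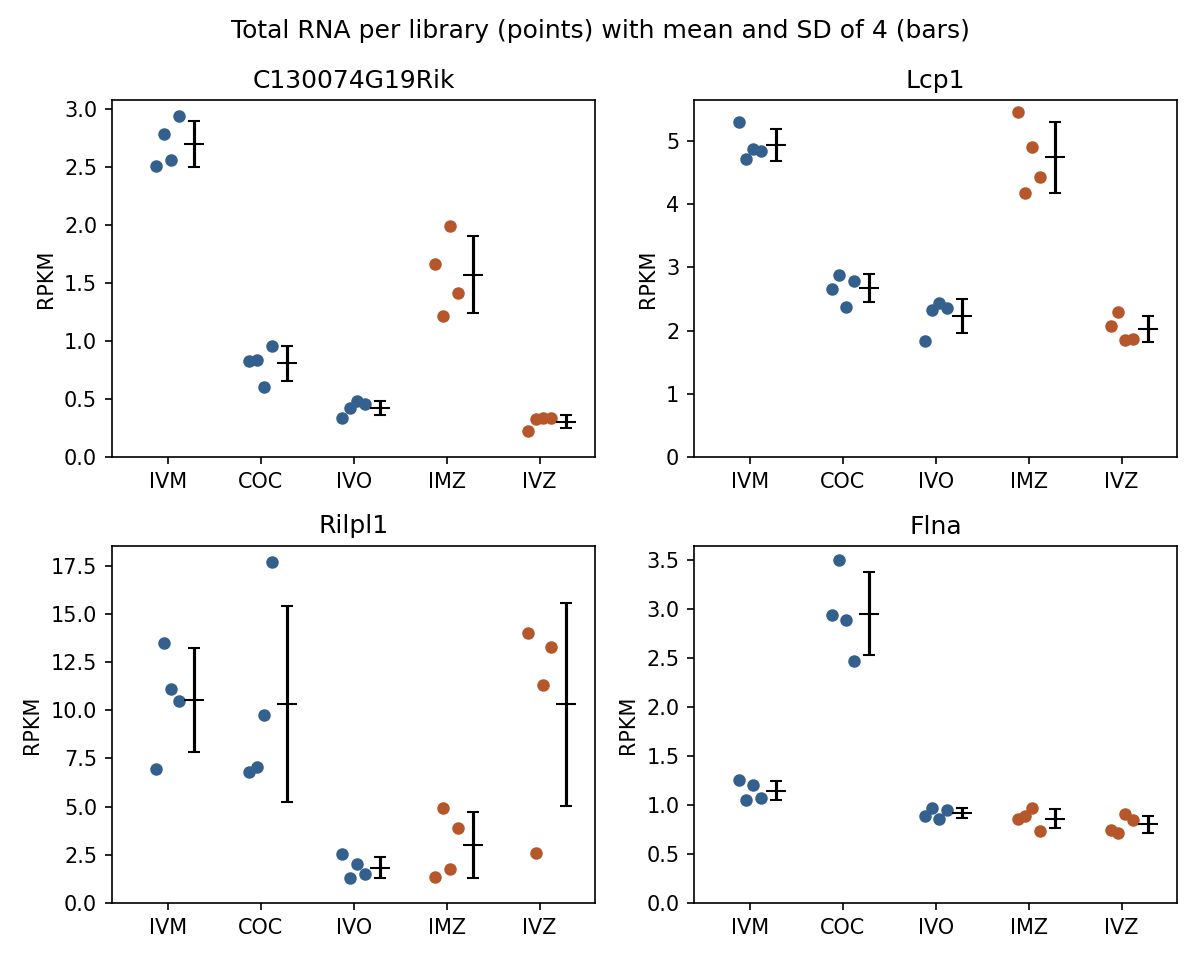
RPKM of 4 genes in total RNA, with a point per library and the mean ± SD of 4 libraries beside each group, on linear axes from 0. C130074G19Rik and Lcp1 stand at 2.70 and 4.93 in IVM oocytes and 1.58 and 4.73 in IMZ zygotes, above the other groups, Flna is highest in COC oocytes at 2.95, and Rilpl1 is low in IVO oocytes at 1.84 and in IMZ zygotes at 3.

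Zygotes from oocytes matured and fertilized in vitro were compared with in vivo zygotes in total RNA. These groups differed in both maturation and fertilization, which cannot be told apart here. Lcp1 was again higher, at 4.73 ± 0.563 in IMZ against 2.03 ± 0.209 in IVZ zygotes (limma adjusted p = 0.0017), and C130074G19Rik, chosen after its values were seen, stood at 1.58 ± 0.33 against 0.308 ± 0.0538 (limma adjusted p = 0.0015). The ribosomal protein genes Rpl41 and Rplp2 rose by 0.88 ± 0.10 and 0.77 ± 0.09, while Rps26 and Rps20 changed by -0.41 ± 0.07 and -0.43 ± 0.08. Cytosolic ribosomal protein genes went both ways, with a median of -0.01 over 81 genes (camera adjusted p = 0.698), 3 higher and 3 lower over all genes, and 6 higher and 6 lower adjusted over the list alone. Rps28, which rose by 0.59 ± 0.12, and Rpl4, at -0.29 ± 0.06, were chosen after their values were seen, and Rpl4 lost its call after median-of-ratios scaling and after removal of the GC or length trend. Also higher were the tubulin gene Tuba1c by 0.74 ± 0.14, the ubiquitin ligase gene Marchf7 by 0.73 ± 0.15 and the chromatin reader gene Zmynd8 by 0.72 ± 0.14, the last not past the threshold after removal of the length trend (0.69). Lower in IMZ zygotes were the Mediator subunit genes Med11, at 4.99 ± 0.412 against 10.9 ± 1.3 (limma adjusted p = 0.0015), and Med20, at 5.05 ± 0.827 against 9.66 ± 1.04. Upf1, the helicase of nonsense-mediated decay, fell from 108 ± 9.65 to 57.7 ± 5.3. Ppp1r15a, which encodes the stress-induced phosphatase subunit GADD34, fell from 40.8 ± 1.54 to 22.2 ± 3.67. The germ cell family genes Pramel48 and Obox2 changed by -0.99 ± 0.17 and -0.87 ± 0.16.

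Of 10824 genes, 55 were higher and 125 lower in IMZ zygotes, and 2047 had an unadjusted p under 0.05. By the authors' deposited table, with their p-values adjusted here, 159 were higher and 270 lower. Of all genes, 1195 (11%) had groups that did not overlap, where chance gives 2.86% for a single gene and genes vary together. No called gene reached a 2-fold change on this scale. The count was 45, 41, 48 and 424 without IMZ replicates 1 to 4 and 34, 321, 95 and 29 without IVZ replicates 1 to 4, and another grouping of the same 8 libraries called 736 genes.

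Mitochondrial ribosomal protein genes were lower as a group in IMZ zygotes, with a median of -0.12 over 75 genes (camera adjusted p = 2.61e-07, and adjusted p = 0.581 with an estimated correlation). Over all genes 6 fell and 0 rose, and adjusted over the list alone 9 fell. Mrps35 stood at 5.46 ± 0.444 against 8.03 ± 0.383, and Mrps31 and Mrpl12 both changed by -0.44, where Mrpl12 lost its call after removal of the length trend (-0.39). Nuclear-encoded genes of oxidative phosphorylation had a median of -0.10 over 76 genes (camera adjusted p = 0.00201, and adjusted p = 0.735 with an estimated correlation), with 4 lower and 1 higher over all genes, and 11 lower and 4 higher adjusted over the list alone. The complex I genes Ndufc2 and Ndufv2 changed by -0.64 ± 0.10 and -0.46 ± 0.08, while Ndufa11, of the same complex, rose by 0.60 ± 0.10.

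Spindle and kinetochore genes had a median of -0.08 in IMZ zygotes (camera adjusted p = 0.00201, and adjusted p = 0.581 with an estimated correlation), with 1 lower and 1 higher over all genes, and 9 lower and 1 higher adjusted over the list alone. Ndc80 fell from 24.1 ± 3.07 to 16.3 ± 2, and Rangap1 rose by 0.60 ± 0.12, a call that ended after removal of the GC trend (0.57). DNA repair genes had a median of -0.07 (camera adjusted p = 0.0273, and adjusted p = 0.511 with an estimated correlation), with 0 passing over all genes and 0 adjusted over the list alone. The list was no longer called at a mean RPKM of at least 1 (camera adjusted p = 0.0633), nor with the replicate number as a block (camera adjusted p = 0.0566). The repair scaffold gene Trp53bp1 differed by -0.31 ± 0.08. Histone genes had a median of 0.12 (camera adjusted p = 0.0273, and adjusted p = 0.735 with an estimated correlation), with 1 higher over all genes and 1 adjusted over the list alone, H3c13, at 163 ± 12.8 against 110.1 ± 7.27. After removal of the GC trend the histone median was 0.08 and the list was no longer called (camera adjusted p = 0.175), and IVZ replicate 2 lay 0.23 above the mean of the zygote libraries. Genes of early zygotic activation had a median of 0.02 (camera adjusted p = 0.728), with 0 passing over all genes, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. Mos stood at 21.4 ± 6.49 against 14.5 ± 4.21 (limma adjusted p = 0.209), and Gdf9, Zp3, Ccnb1, Btg4, Nlrp5 and Dppa3 differed by 0.17, -0.21, -0.13, -0.08, -0.09 and 0.02, none past the threshold.

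The changes in oocytes and zygotes were set side by side over 10679 genes of total RNA, a comparison added after the data were seen. The sample titles do not say whether the oocytes of IMZ zygotes matured denuded, as in IVM, or inside their complexes, as in COC. Higher in both IVM oocytes and IMZ zygotes were 7 genes, where 49 and 55 genes were higher in each and independent lists would share 0.252. Besides C130074G19Rik and Lcp1 these were Hsf2, the chromatin remodelling subunit gene Dpf2, the transcription elongation gene Eloa, the guanylate-binding protein gene Gbp7 and Heca. Hsf2 rose by 0.53 ± 0.09 in oocytes and 0.40 ± 0.06 in zygotes, and Gbp7 by 0.55 ± 0.09 and 0.39 ± 0.07. Dpf2, Eloa and Heca rose by 0.59, 0.55 and 0.56 in oocytes and by 0.30, 0.49 and 0.38 in zygotes. After median-of-ratios scaling Hsf2, Gbp7, Dpf2 and Eloa no longer passed in oocytes, nor did Hsf2, Gbp7 and Eloa after removal of the length trend. The changes across genes correlated with a Pearson r of 0.375, and genes are not independent replicates. In 3 genes the change differed between the stages by the test of the difference. Rilpl1 had a log2 fold change of 2.01 in oocytes and -1.41 in zygotes (limma adjusted p of the difference = 0.04), although its fall in zygotes did not pass alone (limma adjusted p = 0.125) and IVZ replicate 2, at 2.59, lay among the IMZ libraries. Med11 differed by -0.06 in oocytes and -0.99 in zygotes, and Ppp1r15a by 0.02 and -0.86 (limma adjusted p of each difference = 0.0053).

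In polysomal RNA no gene was called in IVM against IVO oocytes. The limma fit gave 0 of 5093 genes, with 152 at an unadjusted p under 0.05, while adjustment of the p-values in the authors' deposited table gave 3 higher and 9 lower. The phospholipid flippase gene Atp11b stood at 3.74 ± 1.64 against 0.797 ± 0.281 and Arfgef2, an exchange factor of ARF GTPases, at 13.1 ± 4.07 against 4.93 ± 1.09. Btbd8 stood at 2.16 ± 0.88 against 0.512 ± 0.19, and the leptin receptor gene Lepr at 1.56 ± 0.621 against 4.14 ± 2.58. These 4 genes were chosen after their values were seen, as genes past 0.05 in the authors' deposited table, and each had a limma adjusted p of 0.985 here. All genes had a median log2 fold change of 0.14, which scaling by the median of ratios moved to -0.01, so list changes were read relative to it.

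Mitochondrial mRNAs had a median of -1.20 over 12 genes in polysomal RNA of IVM oocytes (camera adjusted p = 3.71e-16, and adjusted p = 0.339 with an estimated correlation). None passed over all genes or adjusted over the list alone, and 5 were lower at an unadjusted p under 0.05. mt-Atp8 stood at 48.2 ± 22 against 183 ± 165, mt-Nd1 at 70.0 ± 44.1 against 159.6 ± 70.5 and mt-Co2 at 68.4 ± 39.5 against 252 ± 277. IVO replicate 2 carried the list 1.73 above the mean of the oocyte libraries, and IVM replicate 4, at 0.42, lay above IVO replicates 1 and 4, at 0.13 and -0.05, against the direction of the median. Cytosolic ribosomal protein genes had a median of -0.11 over 77 genes (camera adjusted p = 0.000564, and adjusted p = 0.931 with an estimated correlation), with 0 passing over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, and Rpl14 differed by -0.77 ± 0.40. The always-named genes ranged from -0.40 ± 0.36 for Ccnb1 to 0.37 ± 0.37 for Gdf9, with Mos at 0.05, Btg4 at -0.29, Zp3 at 0.33, Dppa3 at -0.27 and Nlrp5 at -0.28.

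In polysomal RNA of COC against IVO oocytes, limma called 0 of 7527 genes, with 394 at an unadjusted p under 0.05. By the authors' deposited table, with their p-values adjusted here, 2 genes were higher and 23 lower. The 2 higher were the transcription factor gene Klf4, at 2.39 ± 1.58 against 0.346 ± 0.0717, and the lipid kinase gene Pip4k2c, at 8.07 ± 1.4 against 2.64 ± 0.581. The centromere protein gene Cenpv stood at 4.56 ± 2.06 against 16.5 ± 11.7. These 3 were chosen after their values were seen. Cytosolic ribosomal protein genes had a median of -0.17 (camera adjusted p = 1.28e-12, and adjusted p = 0.496 with an estimated correlation) beside a median of 0.18 for all genes, with 0 passing over all genes, 6 lower and 1 higher at an unadjusted p under 0.05 and, adjusted over the list alone, 1 lower. Rpl38 stood at 46.5 ± 17.9 against 110.3 ± 11.5.

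Mitochondrial mRNAs had a median of -0.73 in polysomal RNA of COC oocytes (camera adjusted p = 1.4e-11, and adjusted p = 0.553 with an estimated correlation), with 0 over all genes and 0 adjusted over the list alone. mt-Atp6 stood at 139 ± 37 against 478 ± 503, where IVO replicate 2 alone had 1231. Around the mean of the oocyte libraries the mitochondrial list lay at 0.13, 1.73, 0.62 and -0.05 in IVO replicates 1 to 4. In COC replicates 1 to 4 it lay at 0.19, -0.02, 0.33 and -0.57. COC replicates 1 and 3 thus lay above IVO replicates 1 and 4, against the direction of the median. Histone genes had a median of -0.08 (camera adjusted p = 0.00115, and adjusted p = 0.99 with an estimated correlation), with H2bc14 at 7.83 ± 5.64 against 65 ± 98.4 and H4c4 at 19.6 ± 9.97 against 38.3 ± 20.5. Spindle genes had a median of -0.10 (camera adjusted p = 0.00329, and adjusted p = 0.99 with an estimated correlation), with Ndc80 at -0.52 ± 0.38, while Birc5, of the same list, stood at 203 ± 58.2 against 137 ± 30.3. In both lists 0 genes passed over all genes and 0 adjusted over the list alone. The histone call ended after removal of the length trend (median -0.10, camera adjusted p = 0.464) and the spindle call after removal of the GC trend (median -0.17, camera adjusted p = 0.0554). Around the mean of the oocyte libraries histones lay at -0.49 and -0.56 in IVO replicates 1 and 2, below the -0.28 to 0.19 of COC libraries and against the direction of the median. Gdf9 differed by 0.38 ± 0.32, Ccnb1 and Mos by 0.17, Btg4 by -0.12, Zp3 by -0.14, Nlrp5 by -0.11 and Dppa3 by 0.06.

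In polysomal RNA of IVM against COC oocytes, limma called 0 of 5018 genes, with 223 at an unadjusted p under 0.05, and adjustment of the p-values in the authors' deposited table gave 0. The fold changes in that table followed the ratio of its group means, without the library the authors excluded, with a Pearson correlation across genes of 0.951, beside at least 0.997 in the other tables, so what its p-values compare is less certain, and genes are not independent replicates. Histone genes had a median of 0.58 over 23 genes (camera adjusted p = 0.000463, and adjusted p = 0.839 with an estimated correlation), with 0 passing over all genes and 1 higher adjusted over the list alone. The list lay at 0.86 and 1.36 around the mean of the oocyte libraries in IVM replicates 3 and 4 but at -0.26 and -0.62 in replicates 1 and 2, beside -0.28 to 0.19 in COC libraries. The gene past the threshold, H3c8, stood at 195 ± 38.5 against 84.8 ± 16.6. H2bc3 stood at 30.8 ± 41.6 against 2.76 ± 3.26, but IVM replicate 1, which the authors excluded, had 92.7. The other IVM libraries ran from 3.76 to 15.5. Spindle genes had a median of 0.22 and mitochondrial mRNAs of -0.45 (camera adjusted p = 0.0462 each, and adjusted p = 0.839 with an estimated correlation), both with 0 over all genes and 0 adjusted over the list alone. The spindle call ended after removal of the GC trend, although the median was then 0.25 (camera adjusted p = 0.07), and both ended at a pseudocount of 0.1 (camera adjusted p = 0.0551 each). With the replicate number as a block the mitochondrial call also ended (camera adjusted p = 0.0755). Around the same mean the mitochondrial list lay at 0.42 in IVM replicate 4 and -0.57 in COC replicate 4, against the direction of its median. The kinesin gene Kif20b stood at 8.64 ± 5.71 against 2.59 ± 1.77, and mt-Cytb at 124 ± 52.6 against 204 ± 63.4. Ccnb1 differed by -0.58 ± 0.29, Zp3 by 0.47 ± 0.35, Dppa3 by -0.32 ± 0.20, Btg4 and Nlrp5 by -0.17, Mos by -0.12 and Gdf9 by -0.02.

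In polysomal RNA of IMZ against IVZ zygotes, limma called 0 of 6336 genes, with 360 at an unadjusted p under 0.05, while the p-values in the authors' deposited table gave 54 higher and 109 lower. Dppa3, a maternal protector of DNA methylation, stood at 419 ± 63.6 against 742 ± 184 (limma adjusted p = 0.777). The securin gene Pttg1 differed by -0.90 ± 0.30, the kinetochore gene Spc25 stood at 7.12 ± 1.68 against 17.7 ± 4.59, and Mos at 54.9 ± 13.1 against 29.5 ± 12.4. Chosen after their values were seen, from the authors' deposited table, were Rce1, a protease of prenylated proteins, at 18.6 ± 5.46 against 5.59 ± 1.6, Clec16a at 3.93 ± 1.54 against 1.11 ± 0.621, Gpatch4 at 1.28 ± 0.648 against 5.85 ± 3.76, Tchp at 1.65 ± 1.47 against 7.78 ± 3.51 and Pdzph1 at 1.83 ± 0.934 against 5.99 ± 1.87.

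Histone genes had a median of 0.53 in polysomal RNA of IMZ zygotes (camera adjusted p = 3.01e-05, and adjusted p = 0.959 with an estimated correlation), cytosolic ribosomal protein genes 0.09 (camera adjusted p = 0.0285, and adjusted p = 0.959 with an estimated correlation) and spindle genes -0.36 (camera adjusted p = 0.0248, and adjusted p = 0.959 with an estimated correlation). In each list 0 genes passed over all genes and 0 adjusted over the list alone. H2ac6 stood at 17.5 ± 6.73 against 6.81 ± 4.52, and Rps12 at 65.5 ± 24 against 26.2 ± 11, while Rpl5 went the other way at 73.6 ± 21.5 against 127 ± 42.3. Without IMZ replicate 3 none of the lists was called and the ribosomal list turned to lower, and after removal of the GC trend the spindle and ribosomal lists were no longer called, at medians of -0.21 and 0.16 (camera adjusted p = 0.0763 each). Histones lay at -0.38 around the mean of the zygote libraries in IMZ replicate 2, and at 0.37 and 0.45 in IVZ replicates 3 and 4, against the direction of their median. All genes had a median of -0.10, which was 0.01 after median-of-ratios scaling. The other always-named genes differed by -0.38 for Ccnb1, -0.36 for Btg4, 0.01 for Gdf9, -0.07 for Zp3 and -0.15 for Nlrp5.

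**Figure D2:**
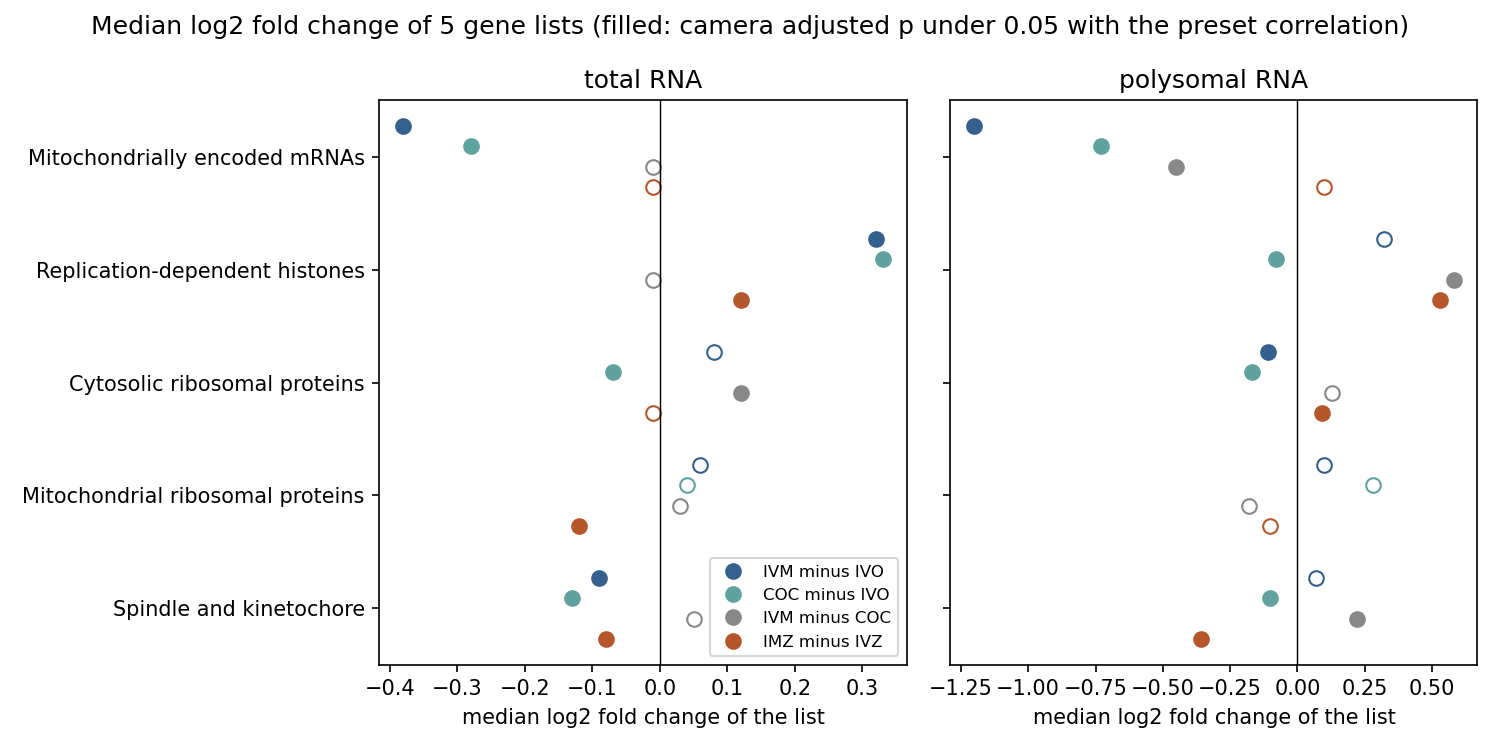
Median log2 fold change of 5 gene lists in the 4 comparisons, total RNA on the left and polysomal RNA on the right, with a separate scale in each panel. Filled points passed camera at an adjusted p under 0.05 with the preset correlation, and the mitochondrial mRNAs lie at -0.38 in total and -1.20 in polysomal RNA of IVM against IVO oocytes; with an estimated correlation no list passed.

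Whether a change in polysomal RNA differed from the change in total RNA was tested gene by gene. Dppa3 had a log2 fold change of -0.80 in polysomal and 0.02 in total RNA of IMZ against IVZ zygotes, a difference of -0.82 ± 0.26 that did not pass (limma adjusted p = 0.916). Mos differed by 0.43 ± 0.43 between the fractions, Ccnb1 by -0.25 ± 0.25 and Gdf9 by -0.16 ± 0.33. In IVM against IVO oocytes the difference was 1.44 ± 0.33 for Atp11b and 1.23 ± 0.32 for Arfgef2 (limma adjusted p = 0.991 for both), genes chosen after their values were seen. In IVM against COC oocytes it was 1.16 ± 0.27 for H3c8 (limma adjusted p = 0.888). The limma interaction called 0 genes in each of the 4 comparisons, with 167, 384, 266 and 311 genes at an unadjusted p under 0.05 in the order IVM against IVO, COC against IVO, IVM against COC and IMZ against IVZ; no other tool was run. In simulated data for IMZ against IVZ, changed on the log2(RPKM + 1) scale, the interaction recovered 5 of 67 genes changed 2-fold. It recovered 49 of 66 changed 4-fold, so differences of 2-fold on this scale were seldom recovered.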

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

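The test of cumulus RNA, the comparison of oocytes with zygotes, the splits of the zygote libraries with the oocyte groups kept and the removal of trends on GC content and length were chosen only after results were seen, as was the description of single zygote libraries.

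Histone genes were higher and mitochondrial mRNAs lower in total RNA of both IVM and COC oocytes than of IVO oocytes. Both groups were compared with the same IVO libraries, so they are not independent repeats. A trend of each library on transcript GC content could raise one list and lower the other, since histone transcripts had a median GC of 59.4% and mitochondrial ones 37.1%. Removing it left 0.73 of the histone median and 0.815 of the mitochondrial one in IVM against IVO (camera adjusted p = 2.02e-06 and 5.03e-05), which argues against GC as the whole cause. Removing the trend on length left 1.28 of the mitochondrial median, which argues against length there, and 0.645 of the histone median in IVM and 0.741 in COC against IVO (camera adjusted p = 5.85e-05 and 8.08e-08), which leaves a part for length open. Neither list passed with an estimated correlation, other splits of the libraries called as many lists, and a difference in maturation stays open and untested.

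C130074G19Rik, Lcp1, Hsf2, Dpf2, Eloa, Gbp7 and Heca were higher in IVM oocytes and in IMZ zygotes. After removal of each library's GC trend all 7 were still called in both, which argues against GC. After removal of the length trend 4 were, as Gbp7, Hsf2 and Eloa missed the threshold in oocytes at 0.52 ± 0.10, 0.51 ± 0.10 and 0.51 ± 0.08 (before, 0.55 ± 0.09, 0.53 ± 0.09 and 0.55 ± 0.08). Their fold changes moved by less than their standard errors, which argues against length as the whole cause of these, although the calls of the 3 genes depend on it. Of 100 drawn pairs of splits 1, the real one, gave 7 shared genes and the highest other 0, but other splits of the oocyte libraries called at most 1 gene and could not share more, and of 35 splits of the zygote libraries with the oocyte groups kept 1 gave 7 (highest other 1) while only 3 called enough genes to reach it, so whether chance gives this sharing stays open. C130074G19Rik and Lcp1 were called in 8 of 8 fits that left out 1 library in either stage, while the others were called in 0 or 1 of 8 in oocytes and 2 to 4 of 8 in zygotes. COC oocytes, also matured in vitro, stood at 0.81 for C130074G19Rik and 2.67 for Lcp1, lower than IVM oocytes at 2.70 and 4.93 (limma adjusted p = 0.000968 and 0.00582). A difference in maturation stays open and untested, and in zygotes it cannot be told apart from a difference in fertilization.

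Flna was higher in COC than in IVM and IVO oocytes, while Plec, Dbn1 and Tes, picked after their values were seen and tested as no list, went the same way without passing, and the actin-bundling gene Lcp1 was lower in COC than in IVM oocytes (2.67 against 4.93). RNA from attached cumulus cells may be a source, since oocytes of this group matured inside their complexes. Of 50 cumulus and granulosa markers 12 were measured in each comparison, with a median of -0.02 ± 0.09 (SE) between COC and IVO oocytes. Between COC and IVM oocytes the median was 0.00 ± 0.05. Grem1 was higher by 0.76 against IVO (limma unadjusted p = 0.000419) and Krt8 lower, at -0.38, against IVM (limma unadjusted p = 0.0201). The 12 markers were not the same set, as Grem1 was measured only against IVO and Kitl only against IVM. The median against IVM thus leaves out Grem1. The tables list only genes detected in all libraries, so markers silent in 1 group are hidden and cumulus RNA cannot be told apart from a change in the oocyte.

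In 3 genes the change differed between zygotes and oocytes by the limma test of the difference. The zygote minus oocyte difference was -3.41 ± 0.55 for Rilpl1, -0.93 ± 0.12 for Med11 and -0.88 ± 0.12 for Ppp1r15a. The real split gave 3 genes and the highest of the other draws 0, so 1 of 100 gave as many, which argues against chance for this count. It does not exclude chance, since the count rests on 3 genes and the comparison was added after the data were seen. Fertilization differed between the zygote groups only, so a difference by stage cannot be told apart from one by fertilization.

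Of 287 groups of 4 values tested, 19 held a library far from the others by Dixon's ratio at its 95% critical value, and chance gives about 1 in 20 groups, or 14.3. In polysomal RNA IVO replicate 2 was highest for mt-Atp6 (ratio 0.923, 1231 against 191 to 271), mt-Co2 (0.874, 664 against 88.8 to 161) and Cenpv (0.864, 33.9 against 8.56 to 12). IVM replicate 1 was highest for Arfgef2 (0.837) and H2bc3 (0.868, 92.7 against 3.76 to 15.5), and IVM replicate 4 for mt-Co2 and Nlrp5 (0.944 each). IVO replicate 3 was highest for H2bc14 (0.908, 212 against 7.53 to 26.4). In total RNA IVM replicate 2 was highest for Eloa (0.836) and Hsf2 (0.857), and IVM replicate 3 for Zfp707 (0.931). COC replicate 3 was highest for Btg4 (0.979), replicate 4 for Mos (0.857) and replicate 2 for H4c8 (0.845), and COC replicate 1 was lowest for mt-Atp6 (0.83). IVO replicate 4 was highest for H4c8 (0.937), IVO replicate 1 lowest for Heca (0.88), IVZ replicate 1 lowest for C130074G19Rik (0.91) and IVZ replicate 3 highest for Ndufc2 (0.833).

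Other splits of the 8 libraries of a comparison, 35 with the real one, were counted. In total RNA 1 of 35 splits, the real one, gave as many genes for IVM against IVO (real 56, highest other 1). The same held for COC against IVO (real 1, highest other 0) and for IVM against COC (real 5, highest other 1). A share of 1 in 35 is the lowest these splits can give, so they argue against chance for these counts but cannot exclude it. For COC against IVO the count rests on 1 gene. For IMZ against IVZ 2 of 35 gave as many (real 180, highest other 736), so chance cannot be excluded. The split with 736 genes put IVZ replicate 2 with IMZ replicates 1 to 3 and IMZ replicate 4 with the other IVZ replicates, shared 8 genes with the real one, and points to a structure of the samples. The 49 genes higher in IVM oocytes, 7 of them also called here, deviated from the mean of the zygote libraries by 0.10 in IMZ replicate 4 and -0.09 in IVZ replicate 2, beside 0.03 to 0.19 in the other IMZ and -0.19 to -0.02 in the other IVZ libraries.

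In polysomal RNA 35 of 35 splits gave as many genes in each comparison, with a real count of 0 and a highest other of 0 for IVM against IVO, 3 for COC against IVO, 0 for IVM against COC and 4 for IMZ against IVZ. For called lists chance cannot be excluded anywhere. In polysomal RNA 27 (real 2, highest other 7), 8 (real 4, highest other 7), 18 (real 3, highest other 6) and 7 (real 3, highest other 4) of 35 splits gave as many lists, in the same order of comparisons. In total RNA 24 (real 4, highest other 8), 9 (real 6, highest other 8), 30 (real 2, highest other 8) and 12 (real 5, highest other 7) did. For polysomal against total RNA 100 of 100 drawn splits gave as many genes as the real 0 in each comparison, and the highest others of 30, 69 and 30 for IVM against IVO, COC against IVO and IMZ against IVZ point to a structure of the samples, while that for IVM against COC was 1.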

How the results depend on the processing

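Array weights, the pairing of fractions by sample code, the pseudocount of 0.1, the mean RPKM of at least 1, no variance trend, GC and length removal and the adjusted authors' p were chosen only after results were seen; the count-based test and count filters were not run, because no counts were used. Where a count changed below, the cause was not tested. In total RNA the 56 genes of IVM against IVO became 11 with median-of-ratios scaling, 117 with all oocyte groups in 1 fit, 34 at a mean RPKM of at least 1, 128 with array weights, 32 after GC removal, 20 after length removal, 104 by the authors' deposited p, 7 at an adjusted p under 0.01, 103 under 0.1 and 4 at 2-fold. The 1 gene of COC against IVO became 4 in the fit of all oocyte groups and 28 by the authors' deposited p. The 5 genes of IVM against COC became 13 in that fit, 36 with array weights, 34 by the authors' deposited p, 13 under 0.1 and 1 at 2-fold. The 180 genes of IMZ against IVZ became 1575 with array weights, 429 by the authors' deposited p, 19 under 0.01, 543 under 0.1 and 0 at 2-fold. In polysomal RNA the authors' deposited p gave 12, 25 and 163 genes for IVM against IVO, COC against IVO and IMZ against IVZ, where limma gave 0. In 0 of 8 comparisons did all 4 same-numbered pairs correlate over 0.1 (range -0.66 to 0.66), and 1 or 2 of 4 correlated best with their own number. In total COC against IVO 3 of 4 pairs were over 0.1, so this rule does not show that replicate numbers are unlinked. With the replicate number as a block the counts in total RNA were 1, 2, 1 and 67 for IVM against IVO, COC against IVO, IVM against COC and IMZ against IVZ. Between polysomal and total libraries, all 8 same-coded pairs correlated over 0.1 in 0 of 4 comparisons (range -0.16 to 0.15). Pairing them by sample code left 0 genes called between the fractions in each. With an estimated inter-gene correlation 0 lists were called in each of the 8 comparisons. A pseudocount of 0.1 left 1 list in polysomal IVM against COC, and the rank-based test left 1 in total IVM against COC. With 1 library left out, genes called ranged from 7 to 52 for total IVM against IVO (7 without IVM 1, IVM 4 or IVO 1, 8 without IVM 3, IVO 2 or IVO 3, 12 without IVO 4), 1 to 2 for COC against IVO (2 without COC 1, COC 4 or IVO 4), 4 to 6 for IVM against COC and 29 to 424 for IMZ against IVZ, and were 0 in polysomal RNA. Polysomal against total RNA ranged from 0 to 1 (1 without polysomal IVO 4 in both IVO comparisons, without IVM 1 or IVM 2 against COC, and without IVZ 2). Lists called ranged in polysomal RNA from 1 to 3 for IVM against IVO (1 without IVO 1), 3 to 5 for COC against IVO, 2 to 3 for IVM against COC and 0 to 4 for IMZ against IVZ (0 without IMZ 3, 1 without IVZ 2 or IVZ 4). In total RNA they ranged from 4 to 8 (8 without IVM 4 or IVO 3), 3 to 6 (3 without IVO 1), 1 to 6 (6 without IVM 3 or COC 3, 1 without COC 2 or COC 4) and 3 to 7 (3 without IMZ 2). The cytosolic ribosomal proteins of polysomal IMZ against IVZ turned to lower without IMZ 3 (adjusted p = 0.828), in a range of 8.38e-05 to 0.83. Of values for single genes, 1543 kept their side of the threshold under the other settings, 57 lost it and 18 gained it. With 1 library left out 1515 kept it, 167 lost it and 6 gained it. Depth is known for 12 of 20 polysomal libraries, the shallowest at 3.14 M reads, and its share in these limits was not compared.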

Other observations

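The tests of lists between fractions were chosen only after results were seen. The change in polysomal RNA set against the change in total RNA differed in the histone list by a median of -0.57 for COC against IVO oocytes, 0.48 for IVM against COC oocytes and 0.45 for IMZ against IVZ zygotes (camera adjusted p = 1.52e-08, 0.00188 and 0.000634). For mitochondrial mRNAs it was -0.88 for IVM against IVO and -0.35 for COC against IVO (camera adjusted p = 4.61e-07 and 0.000157), and for cytosolic ribosomal proteins -0.20 and -0.15 (camera adjusted p = 1.34e-06 and 2.77e-06). In IMZ against IVZ zygotes cytosolic ribosomal proteins differed by 0.13 and nuclear-encoded genes of oxidative phosphorylation by 0.12 (camera adjusted p = 0.0455 for both). Beside these, all genes had a median difference of 0.12 for IVM against IVO, 0.18 for COC against IVO, -0.06 for IVM against COC and -0.09 for IMZ against IVZ. The mitochondrial list lay 1.73 above the mean of the oocyte libraries in polysomal IVO replicate 2, as given above. No list passed with an estimated correlation, where the lowest adjusted p was 0.522.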
